A study of Mus musculus with 15 samples.

How the data were processed

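Dendritic cells were taken from the thymus of Itgax-cre Stk11 fl/fl mice (KO) and of WT mice, male and female, on the C57BL/6 background. Per the labels, mice aged 8 to 12 weeks carried a subcutaneous B16 melanoma that secreted Flt3L, a growth factor that expands dendritic cells. Thymi were collected 9 to 12 days after the injection. After enrichment on CD11c beads, cells positive for CD11c and MHC class II were sorted into cDC1 by CD8a and into cDC2 by CD11b, and pDC were sorted by Siglec-H and intermediate CD11c. Libraries were strand-specific 3′ tags from barcoded oligo-dT primers, pooled after first-strand synthesis and amplified by 12 cycles of PCR.

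The deposited table held raw read counts per gene, 1 column per library, with no normalization by the authors. The submitters' processing notes name STAR, HTSeq, DESeq2 and mm10. Which of them aligned and which counted the reads, their versions and the treatment of duplicate reads are not given in the sources used here. The values were checked to be whole numbers. The table had 22165 genes, of which 21822 matched a symbol and 21522 were protein coding in GENCODE M21 (GRCm38), which gave the coordinates, and 5860 had no count in any library.

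Genes were kept by edgeR's filterByExpr on the 6 groups, which left 11746 genes, and the genes left out held 0.0538% of the counts. Libraries were scaled by TMM factors (0.841 in pDC WT 3 to 1.08 in cDC2 KO 1). A quasi-likelihood model with robust spread and 1 coefficient per group was fitted to the 15 libraries with edgeR 4.0.16 in R 4.3.3 (common biological coefficient of variation 0.395). Contrasts were KO minus WT in each subset, their average over the 3 subsets with equal weight, the 3 differences of these effects between subsets, and the 3 comparisons of WT subsets. P-values were adjusted over all tested genes by the Benjamini-Hochberg method, with a threshold of 0.05, and are two-sided. Folds against a group at 0 use a floor of 3 counts over the group. Groups of 2 libraries rest on the spread pooled over the groups.

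There were 31 gene lists with 607 symbols, of which 596 were in the table and 544 tested. They covered markers of the 3 subsets, dendritic cell maturation, costimulation, antigen presentation, LKB1 and AMPK-related kinases, CREB targets, phospholipase C and calcium signalling, ATF4, glycolysis, oxidative phosphorylation, fatty acid oxidation, cholesterol synthesis, lysosome, interferon, NF-kB, chemokines, cell cycle, p53, dissociation stress, sex-linked genes and 8 other cell types. With at least 3 tested members required, 30 could be tested, and the melanoma list could not. Lists were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the 30 lists of a comparison. Camera with an estimated correlation and fry were run as alternatives. Members were also adjusted over the list alone.

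Contrasts, tests, gene lists, the alternatives and the rule for named genes were chosen before the data were examined. In each genotype comparison, the rule took the genes past the threshold whose groups did not overlap (for the average, with 1 sign in all 3 subsets), up to 12 with the smallest p in each direction. It passed over genes without an informative name. For each list it took up to 4 members with the smallest p, and it took Stk11, Ccr7, Tnfsf4, Plcb1, Xist and Ddx3y whatever their values. Differences between subsets gave up to 6 genes past the threshold, otherwise 2, and WT comparisons 8 per direction. Of the genes it took, the text names those that carry a comparison, and some results are not reported here.

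Alternatives were RLE scaling, DESeq2 1.42.0, limma voom with sample quality weights, no filter, a strict filter at 10 CPM, only the groups of the contrast, the spread without robust estimation, a threshold of 0.1, a fold threshold, the replicate number as a block, and leaving out each library in turn. Per-library offsets for transcript length and GC content, and the average without the cDC2 libraries, were added after the data had been seen. The test was run on simulated counts with known changes of 2-fold, 4-fold and 8-fold, where it recovered 92.4% to 95.5% of the 66 genes changed 8-fold and called 3, 10 and 8 unchanged genes in cDC1, cDC2 and pDC. The changed genes were drawn only from those above a minimum mean expression in the subset. Of 99 random lists of 25 genes, camera called 0, and it called the list raised 1.5-fold. The simulated genes varied independently of each other. That check therefore does not cover lists whose genes move together. Replicates of a group differed by more than counting error, with a chi-square per degree of freedom of 27.9 to 101.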

Results

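Gene expression was measured by 3′ RNA sequencing in 3 dendritic cell subsets sorted from mouse thymus, each from wild-type (WT) mice and from mice lacking the kinase LKB1 in CD11c-expressing cells (KO). LKB1, encoded by Stk11, activates AMPK and related kinases and so links cell metabolism to growth and polarity. The subsets were conventional dendritic cells of type 1 (cDC1), which cross-present antigen, conventional dendritic cells of type 2 (cDC2), which carry CD11b, and plasmacytoid dendritic cells (pDC), which are specialised interferon producers. There were 15 libraries in 6 groups: 2 cDC1 KO, 2 cDC1 WT, 3 cDC2 KO, 2 cDC2 WT, 3 pDC KO and 3 pDC WT. Total counts per library ran from 3928164 (cDC2 WT 1) to 12142712 (cDC2 KO 2), with 4105082 to 7490137 in cDC1 and 5453387 to 10499062 in pDC. The labels do not say that the replicates came from separate mice, so each p-value below measures the spread between samples. Adjusted p-values for genes come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 11746 tested genes. Expression is given in CPM, counts scaled to the effective library size, as mean ± SD over the libraries of a group, and log2 changes carry their standard error. The data hold no molecular identifiers, so floors for groups at 0 cover counting error only.

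**Figure D1:**
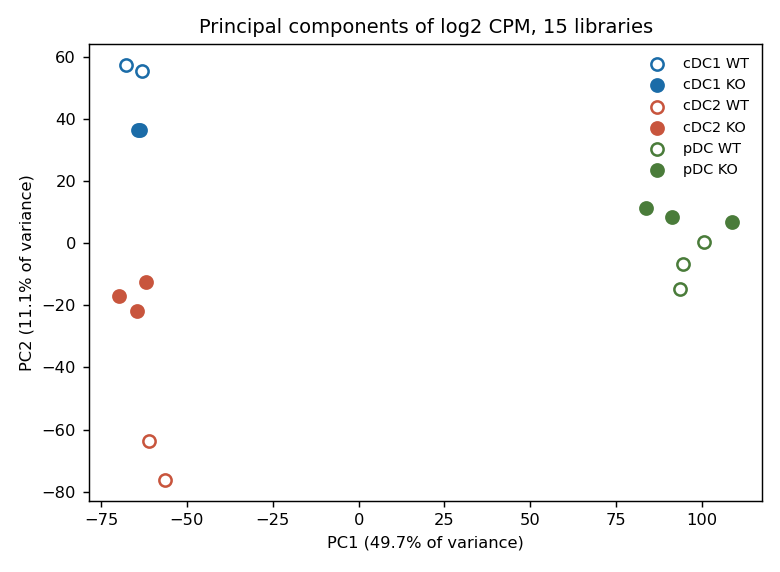
Principal components 1 (49.7% of the variance) and 2 (11.1%) of log2 CPM for the 15 libraries, coloured by subset, filled for KO and open for WT. The pDC libraries lie apart from both cDC subsets on the first component, and the 2 cDC2 WT libraries lie below the 3 cDC2 KO libraries on the second.

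The WT subsets differed by the genes that define them, which checks the sort labels. Itgam, which encodes CD11b, stood at 103 ± 2.07 CPM in cDC2 WT (n = 2) against 1.12 ± 1.07 in cDC1 WT (n = 2), a log2 difference of 6.59 ± 0.58 (adjusted p = 7.91e-06), and Sirpa was 14.1-fold higher in cDC2. Cd8a, used to sort cDC1, was 18.1-fold lower in cDC2 WT than in cDC1 WT (adjusted p = 7.91e-06), and Cd207, which encodes langerin, was at least 195-fold lower, with 0 counts in cDC2 against 509 (floor of 3 counts over the group). Siglech, the surface lectin used to sort pDC, reached 20814 ± 6237 CPM in pDC WT (n = 3), 176-fold above cDC1 and 102-fold above cDC2, and Ly6d and the transcription factor gene Spib were also higher in pDC in both comparisons. The cDC1 genes Naaa and Wdfy4 were lower in pDC, Naaa 82.1-fold against cDC1 and Wdfy4 13.2-fold against cDC2. In all, 1025 genes differed between cDC2 and cDC1 (440 higher and 585 lower in cDC2), 3253 between pDC and cDC1 (1509 and 1744) and 2771 between pDC and cDC2 (1336 and 1435). The marker lists moved with the labels: the cDC2 list had a median log2 difference of 2.61 between cDC2 and cDC1 (camera, adjusted p = 2.93e-16, and 0.00716 with an estimated correlation), the cDC1 list −1.96 (1.32e-09, and 0.00716), and the pDC list 5.48 between pDC and cDC1 (7.36e-47, and 0.000218). The cell cycle list was lower in pDC than in cDC2, with a median of −2.02, all 30 genes negative and 24 past the threshold (camera, adjusted p = 5.55e-16, and 0.0466 with an estimated correlation). Leaving out cDC1 WT 1 or cDC1 WT 2 brought the count between cDC2 and cDC1 down to 253 or 340, and leaving out cDC2 WT 2 to 574. The balance between higher and lower genes in cDC2 against cDC1 turned with the method, to 548 and 500 with RLE scaling, 717 and 645 without a filter, and 431 and 251 with offsets for length and GC content. For pDC against cDC1 it turned to 1598 and 1339 with the offsets and to 1599 and 1511 with the strict filter. The count between pDC and cDC1 was 1692 without cDC1 WT 1 and 2128 without cDC1 WT 2.

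Stk11 itself, the targeted gene, was read at 24.5 ± 8.65 CPM in cDC1 KO against 44.9 ± 13.2 in cDC1 WT (n = 2 each). It was read at 31.2 ± 4.29 against 34.6 ± 0.501 in cDC2 (n = 3 and 2) and at 37.8 ± 5.25 against 51.4 ± 13.7 in pDC (n = 3 each). Per library, Stk11 ranged from 18.4 to 30.6 CPM in cDC1 KO, from 35.7 to 54.3 in cDC1 WT, from 28.2 to 36.1 in cDC2 KO, from 34.2 to 34.9 in cDC2 WT, from 33.2 to 43.5 in pDC KO and from 40.6 to 66.8 in pDC WT. Its log2 difference, KO minus WT, was −0.88 ± 0.36 in cDC1, −0.15 ± 0.33 in cDC2 and −0.44 ± 0.29 in pDC, and −0.49 ± 0.19 averaged over the subsets (adjusted p = 0.387). None of the 4 values passed the threshold (adjusted p = 1, 0.891, 0.633 and 0.387). The libraries hold 3′ tags and the labels do not place the deleted part, so tags outside it would remain and this level checks nothing about the deletion.

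In cDC1, loss of LKB1 was compared within the subset that takes up and cross-presents antigen in the thymic medulla. Cox6a2, a cytochrome c oxidase subunit of muscle that pDC also express, was 61.4-fold higher in KO, at 33.3 ± 0.512 CPM against 0.586 ± 0.829 (n = 2 each; log2 5.94 ± 0.71, adjusted p = 0.00167). Plcb1, a phospholipase C that turns G protein signals into calcium release, had 94 counts in KO against 0 in WT, at least 21.0-fold higher (6.47 ± 0.283 CPM; adjusted p = 0.0431). Itgam was 10.8-fold higher (11.5 ± 2.24 against 1.12 ± 1.07 CPM; adjusted p = 0.0431). These 3 genes were the only ones past the threshold, all higher in KO. A further 447 genes had an unadjusted p under 0.05 without passing, 3.83% of tested genes with the called ones included. That share is not above what a threshold of 0.05 gives without any difference. DESeq2 called 14 genes, the same 3 among them. Cox6a2 kept its call without any 1 of the 15 libraries, with a log2 difference of 4.81 without cDC1 WT 2 and 10.89 without cDC1 WT 1, where the remaining WT library had 0 counts. Plcb1 and Itgam sat close to the threshold: leaving out 9 and 11 of the 15 libraries in turn ended their calls, among them both cDC1 KO libraries and cDC1 WT 2, and Itgam moved to 2.61 without cDC1 WT 2 and 4.91 without cDC1 WT 1. The transcript Gm49368 overlaps Itgam on the same strand, so reads in the shared part cannot be assigned to either with certainty.

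Among the gene lists in cDC1, 8 of 30 passed camera's threshold. The thymocyte and T cell list was lower in KO, with a median of −0.76 and 17 of 19 genes negative, Thy1 (−1.36 ± 0.52) and Cd8b1 (−0.94 ± 0.42) among them (camera, adjusted p = 7.29e-06, and adjusted p = 0.255 with an estimated correlation). The type I interferon response list was higher, with a median of 0.58 and 24 of 27 genes positive, led by Ifit1 at 33.0 ± 5.16 against 13.7 ± 2.19 CPM and by Ifih1 and Oas2 (adjusted p = 8.55e-05, and 0.255 with an estimated correlation). The interferon call ended without cDC1 WT 1 (median 0.37, adjusted p = 0.116), and the median was 0.30 without cDC1 KO 1. The thymocyte median was −0.35 without cDC1 KO 2 and −0.34 without cDC1 WT 2, with the call kept. The pDC marker list was higher with a median of 0.30, Cox6a2 and Atp1b1 at its top (4.83e-05, and 0.255 with an estimated correlation), and the cDC2 marker list with a median of 0.34, where Sirpa (1.09 ± 0.33) also passed adjusted over the list alone (0.0498, and 0.559). The cDC1 marker list was lower with a median of −0.32, Cd8a at 128 ± 19.2 against 254 ± 6.59 CPM and Irf8 at 3292 ± 305 against 5214 ± 684 (0.0198, and 0.255 with an estimated correlation). The chemokine list was lower with a median of −0.30 (0.0238, and 0.349 with an estimated correlation). The MHC class II list was lower with a median of −0.05 and a mean of −0.16, H2-Aa at −0.55 ± 0.25 (0.0218, and 0.255 with an estimated correlation). The cell cycle list was higher with a median of 0.24 and 28 of 30 genes positive, Top2a at 1.10 ± 0.33 (0.0218, and 0.678 with an estimated correlation). The cell cycle median was −0.12 without cDC1 WT 2 and 0.0026 without cDC1 KO 2 (adjusted p = 0.705 and 0.845). Without cDC1 WT 2 the calls for pDC markers (median 0.32, adjusted p = 0.0887), cDC2 markers (0.21, 0.605) and cDC1 markers (−0.17, 0.236) also ended. Without cDC1 WT 1 the medians of the pDC and cDC2 marker lists were 0.66 and 0.67, with both calls kept. Without cDC1 KO 2 those for cDC1 markers (median −0.31, adjusted p = 0.108) and cDC2 markers (0.16, 0.167) ended, without cDC1 KO 1 or cDC1 WT 1 those for MHC class II (0.0941 and 0.0887) and chemokines (0.301 and 0.260). The MHC class II medians were then −0.39 and −0.26, further from 0 than with all libraries, and the chemokine medians −0.10 and −0.06. With offsets for length and GC content the MHC class II median was −0.11 and its call stayed (0.0488), where the offsets shifted all tested genes by a median of −0.056. The chemokine call also ended without either cDC2 WT library (median −0.20 each, adjusted p = 0.0619 and 0.0612), and that for cDC2 markers without cDC2 KO 1, cDC2 KO 2 or pDC KO 2 (0.0553, 0.0505 and 0.0519, medians 0.34, 0.32 and 0.34). Mean scores of several lists not past camera's threshold also lay higher in both cDC1 KO libraries, as 1 in 6 splits gives by chance. Among them were NK cells (2.18 and 1.47 log2 CPM against 1.18 and 0.68), monocytes and neutrophils (0.06 and −0.13 against −0.31 and −0.36) and dissociation stress (9.13 and 9.01 against 8.66 and 8.73). Another was MHC class I presentation, with a mean difference of 0.12. No gene of the interferon, thymocyte, cell cycle or MHC class II lists passed the threshold over all tested genes.

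In cDC2, Plcb1 was the gene with the smallest p, at 65.0 ± 10.02 CPM in KO (n = 3) against 0.678 ± 0.959 in WT (n = 2), 80.7-fold higher (log2 6.33 ± 0.68, adjusted p = 0.00146). The membrane glycoprotein gene Gpm6b (93 counts against 0) and Tspyl3 (94 against 0) were at least 13.0-fold and at least 12.9-fold higher. S100a11, a calcium-binding protein, rose 2.72-fold to 582 ± 77.6 CPM, and the interferon-inducible Ifi27l2a rose 3.09-fold to 282 ± 23.0. The adaptor gene Gab3, the arginine synthesis gene Ass1 and the chromatin gene Ino80c were 8.73-fold, 5.43-fold and 14.5-fold higher. Lower in KO were Cd4 (4.57 ± 1.06 against 20.4 ± 12.3 CPM; adjusted p = 0.0323), the calcium-sensing membrane gene Mctp2 (0.532 ± 0.307 against 4.09 ± 1.67; adjusted p = 0.0323), Syne2 (3.10-fold) and Paqr5 (14.3-fold). In all, 14 genes passed, 10 higher and 4 lower, 9 of them with an adjusted p of 0.0496 close to the threshold, and 1564 genes (13.3%) had an unadjusted p under 0.05. RLE scaling and the offsets for length and GC content each left 2 higher and 3 lower. Those 14 were also called by DESeq2 among 222 genes and none of them by limma voom with sample weights, which called 0. Without cDC2 KO 1, 2 or 3, or cDC2 WT 1 or 2, 1, 3, 2, 4 and 3 of the 14 calls remained, and without 1 of the other 10 libraries 4 to 14 did. Plcb1 kept its call in all 15, at 11.85 without cDC2 WT 2, the WT library that held its counts, and 5.58 without cDC2 WT 1. Without cDC2 WT 2, Cd4 was −1.35 (adjusted p = 0.115), Gab3 4.54, Ino80c 9.62 and Paqr5 −2.87, and without cDC2 KO 2, Paqr5 was −7.50 and Mctp2 −3.53. Mctp2 lost its call without cDC2 KO 1, cDC2 KO 3 or cDC2 WT 2 (0.0789, 0.0898 and 0.102).

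The lists in cDC2 were dominated by genes higher in KO. The type I interferon list had a median of 0.68 with 24 of 27 genes positive, Isg15 at 182 ± 19.8 against 53.8 ± 15.3 CPM and Ifit1 at 348 ± 75.4 against 119 ± 47.4 (camera, adjusted p = 0.000109, and adjusted p = 0.266 with an estimated correlation). 5 of its genes passed adjusted over the list alone and 0 over all genes. The oxidative phosphorylation list had a median of 0.51 with 48 of 55 genes positive, Atp5f1 at 1.22 ± 0.29 (0.000152, and 0.614). The MHC class I list had a median of 0.56, Tapbpl at 1.36 ± 0.36 (0.00895, and 0.266 with an estimated correlation), and the MHC class II list 0.51, Ctsz at 1.17 ± 0.25 (0.0147, and 0.266). Cholesterol and fatty acid synthesis had a median of 0.50, with Fdft1 at 2.34 ± 0.67 and Srebf2 at 1.05 ± 0.32 (0.0206, and 0.474 with an estimated correlation). Dendritic cell maturation had a median of 0.64, with Fscn1 at 1.79 ± 0.71 against Ccl17 at −2.63 ± 0.69 (0.0450, and 0.954). Lower in KO were the thymocyte and T cell list, with a median of −0.81 (0.000109, and 0.266), and the cDC1 marker list, with a median of −0.26, Wdfy4 at −0.74 ± 0.24 (0.0147, and 0.266 with an estimated correlation). Mean scores of the remaining lists of other cells, none past camera's threshold, also moved in cDC2 KO. Monocytes and neutrophils were higher by 1.09 (1.00 to 1.31 log2 CPM in KO against 0.09 and 0.15 in WT). NK cells were higher by 1.36, with groups that overlapped (3.03, 2.10 and 0.83 against 0.95 and 0.31). The differences were 0.42 for thymic epithelium and stroma, 0.28 for B cells, −0.07 for macrophages and −0.09 for erythroid cells. The thymocyte call rested on cDC2 WT 2: without it the median was 0.00058 and the call ended (adjusted p = 0.168). Without cDC2 WT 1 the median of cDC1 markers was 0.32 (adjusted p = 0.766), and the calls for MHC class I (0.307), MHC class II (0.139), cholesterol synthesis (0.167) and maturation (0.516) ended. Their medians were then 0.58, 0.53, 0.62 and 0.49, so the calls ended with fewer libraries while the medians mostly did not shrink. Those for MHC class II ended also without cDC2 WT 2 or cDC2 KO 3 (0.0845 and 0.0667, medians 0.52 and 0.45), for maturation without cDC2 KO 1 or 3 (0.101 each, medians 0.54 and 0.62), for cholesterol synthesis without cDC2 KO 2 (0.0706, median 0.43) and for cDC1 markers without cDC2 KO 2 or 3 (0.0565 and 0.0640, medians −0.22 and −0.21). The cDC2 WT libraries were of lower complexity, with 10700 and 11267 genes detected at equal depth against 12184 to 12559 in cDC2 KO, and 3.93% ± 0.150 of counts in ribosomal protein genes against 5.32% ± 0.421. Their log2 CPM, relative to each gene's mean over all libraries, also rose with transcript length. Spearman's rho was 0.157 and 0.180, against −0.145 to −0.0421 in cDC2 KO, over genes that are not independent replicates. This trend was not particular to cDC2 WT, as rho ran from 0.0384 to 0.185 in pDC WT and from −0.0314 to 0.0810 in pDC KO. With offsets for length and GC content, added after the data were seen, the medians were 0.0085 for oxidative phosphorylation (adjusted p = 0.760), 0.27 for MHC class I (0.356), −0.09 for MHC class II (0.760) and 0.27 for maturation (0.227), and these 4 calls ended. The cDC1 marker list moved to −0.58 with its call kept (0.0141). The offsets shifted all tested genes in cDC2 by a median of −0.23, so part of each of these moves is not particular to the list.

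In pDC, where 3 libraries stood against 3, Plcb1 had 1092 counts in KO and 0 in WT, at least 443-fold higher (54.8 ± 15.5 CPM; adjusted p = 1.03e-05). Its neighbour Plcb4, another phospholipase C beta gene, rose 5.32-fold to 159 ± 88.3 CPM from 29.9 ± 4.68 (adjusted p = 0.0254). Itgam rose 12.8-fold, to 65.8 ± 2.70 CPM from 5.14 ± 2.46 (log2 3.68 ± 0.38, adjusted p = 0.000112). The nucleotide synthesis gene Rrm2 rose 5.55-fold (adjusted p = 0.0249) and the phosphodiesterase gene Pde8a 20.3-fold (3.73 ± 0.380 against 0.174 ± 0.301 CPM, from 73 and 4 counts; adjusted p = 0.0342). The kinesin gene Kif1a was at least 18.5-fold lower, with 0 counts in KO against 68 in WT (adjusted p = 0.0154). In all, 8 genes passed, 7 higher and 1 lower, and 1245 genes (10.6%) had an unadjusted p under 0.05. DESeq2 called 137 (72 higher and 65 lower), these 8 among them, and edgeR without a filter called 113 higher and 90 lower. Plcb1 and Itgam kept their calls without any 1 of the 15 libraries. Plcb4 lost its call without pDC KO 2 or 3 or without any 1 pDC WT library, Rrm2 without pDC KO 2 or any 1 pDC WT library, and Kif1a without pDC KO 2 (adjusted p = 0.0692). Pde8a moved to 7.71 without pDC WT 1 and 3.74 without pDC WT 3, and its call ended without 9 of the 15.

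3 lists passed in pDC, all higher in KO, and 2 to 11 did with 1 library left out, 11 of them without pDC KO 3 and 6 without pDC WT 3. The type I interferon list had a median of 0.67 with 25 of 27 genes positive, and 7 genes passed adjusted over the list alone, among them the interferon regulator Irf7 at 301 ± 27.7 against 111 ± 33.2 CPM and Oasl1 at 20.6 ± 8.23 against 7.15 ± 1.51 (camera, adjusted p = 1.85e-09, and adjusted p = 0.225 with an estimated correlation). None of them passed over all genes. The cell cycle list had a median of 0.48, with Rrm2, Aurkb and Ube2c at its top (0.000926, and 0.759 with an estimated correlation), and its call ended without pDC KO 2, where the median was 0.29 (0.0544), and without pDC WT 3, where it was 0.34 (0.0628). The oxidative phosphorylation list had a median of 0.25 (0.000683, and 0.759) and lost its call with the offsets for length and GC content (0.0582) and without pDC WT 3 (median 0.10, adjusted p = 0.191). Of the costimulation genes, Cd86 (2.23-fold higher), Icosl (2.08-fold higher) and Pdcd1lg2 (8.02-fold lower, 9 counts against 93) passed adjusted over their list alone and not over all genes (adjusted p = 0.211, 0.297 and 0.267). The maturation chemokine receptor gene Ccr7 had log2 differences of 0.49 ± 0.85 in cDC1, 1.65 ± 0.82 in cDC2 and 1.95 ± 0.72 in pDC, none past the threshold (adjusted p = 1, 0.403 and 0.404). In pDC its counts per library were 271, 213 and 16.8 CPM in KO 1, 2 and 3, against 32.3, 41.0 and 56.2 in WT, so that KO 3 lay below every WT library.

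**Figure D2:**
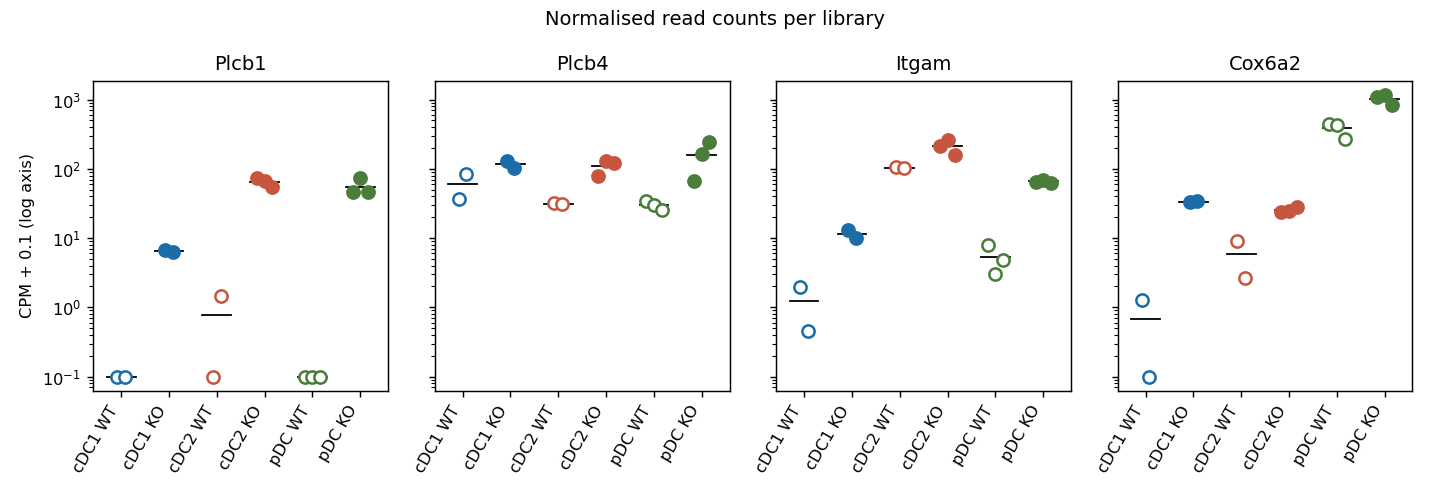
CPM per library (log axis, 0.1 added) of Plcb1, Plcb4, Itgam and Cox6a2 in the 6 groups, with KO filled, WT open and group means as bars. Plcb1 has 0 counts in 6 of the 7 WT libraries, and Itgam stands at 65.8 CPM in pDC KO against 5.14 in pDC WT.

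Averaged over the 3 subsets, KO minus WT, 36 genes passed, 28 higher and 8 lower. Plcb1 (adjusted p = 6.45e-07), Itgam (log2 2.71 ± 0.26, adjusted p = 3.56e-05) and Cox6a2 (3.19 ± 0.32, adjusted p = 3.82e-05) led, followed by Plcb4 (1.73 ± 0.26, adjusted p = 0.00946). Also higher were Cotl1, which binds F-actin (1.08 ± 0.17), Auts2 (1.96 ± 0.32), the drug transporter gene Abcb1a (42.5 ± 3.60 against 5.62 ± 3.13 CPM in cDC2) and the interferon-induced Ifitm2 (2.57 ± 0.44), Ifit1 (1.15 ± 0.20), Isg15 (1.06 ± 0.21) and Rsad2 (0.87 ± 0.17). Lower were the calcium channel genes Cacna1e (−1.37 ± 0.21, adjusted p = 0.00946) and Cacnb2 (−0.98 ± 0.20), the nuclear receptor gene Rxra (−1.16 ± 0.24) and its target, the cholesterol exporter gene Abca1 (−1.48 ± 0.29), Tns1 (−1.02 ± 0.21), Srcap (−0.89 ± 0.18) and Kif1a. DESeq2 called 133 genes, all 36 among them. Plcb1 lies on chromosome 2 from 134786067 to 135475258 and Plcb4 from 135659011 to 136014593. Itgam (128062640 to 128118491) and Cox6a2 (128205435 to 128206387) lie on chromosome 7 on either side of Itgax (GRCm38), whose own difference was 0.30 ± 0.14 (adjusted p = 0.50). Plcb1, Itgam and Cox6a2 kept their calls without any 1 library, with Cox6a2 at 4.82 without cDC1 WT 1. Plcb4 lost its call without cDC1 WT 1 (adjusted p = 0.0533), Cacna1e without cDC1 KO 2 or cDC1 WT 2 (0.0624 and 0.0509), Ifit1 without 7 of the 15 libraries, Isg15 and Rsad2 without 12 each. Without cDC1 WT 1 or 2, 5 of the 36 calls remained, without cDC1 KO 1 or 2, 6 and 7, without cDC2 KO 1, 2 or 3, 11, 8 and 13, without cDC2 WT 1 or 2, 11 and 19, and without pDC KO 1 or 2, 18 and 22. Without the 5 cDC2 libraries, an alternative added after the data were seen, only Plcb1, Itgam and Cox6a2 stayed past the threshold.

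**Figure D3:**
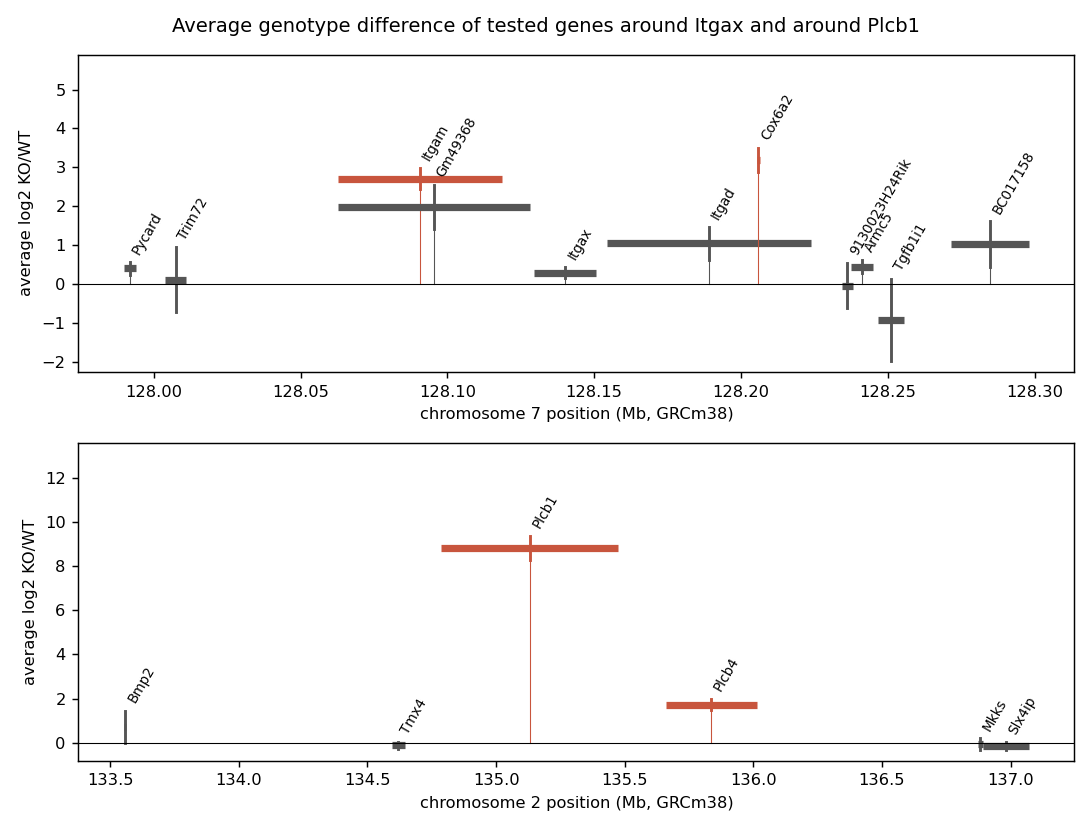
Average log2 difference, KO minus WT, of tested genes around Itgax on chromosome 7 and around Plcb1 on chromosome 2, against position in megabases; horizontal bars span each gene, vertical bars show 1 standard error, and genes with an adjusted p under 0.05 are red. Itgam and Cox6a2 stand at 2.71 and 3.19 on either side of Itgax at 0.30, and Tmx4, Mkks and Slx4ip beside Plcb1 and Plcb4 lie between −0.14 and −0.06.

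The type I interferon response list moved furthest in the average by its test: all 27 tested genes were higher in KO, with a median of 0.77 (camera, adjusted p = 6.32e-15, and adjusted p = 0.0540 with an estimated correlation). 10 of them passed adjusted over the list alone, and Ifit1, Isg15 and Rsad2 over all genes. Fry, which asks whether the genes of a list move 1 way without comparing them with other genes, gave 0.00838. The thymocyte and T cell list was lower with a median of −0.63 and 18 of 19 genes negative, Cd4 at −0.91 ± 0.21 and Satb1 at −0.63 ± 0.17 (4.17e-08, and 0.149 with an estimated correlation). Higher were cell cycle (median 0.39; 2.18e-05, and 0.372), oxidative phosphorylation (0.26; 0.000152, and 0.632), MHC class I presentation (0.26; 0.00133, and 0.174), dendritic cell maturation (0.40; 0.00289, and 0.647), cholesterol and fatty acid synthesis (0.20; 0.0183, and 0.482) and dissociation stress (0.28; 0.0207, and 0.632), with the second value of each pair taken with an estimated correlation. Lower were cDC1 markers (−0.30; 0.0175, and 0.256) and macrophages (−0.22; 0.0183, and 0.208), with C1qc at −1.72 ± 0.57. No list in any of the 4 genotype comparisons held with an estimated correlation. With offsets for length and GC content the median of oxidative phosphorylation was 0.034 (adjusted p = 0.376), of MHC class I 0.14 (0.0547) and of dissociation stress 0.10 (0.0752), and those calls ended, while the interferon list stood at 0.68. The macrophage list moved from −0.22 to −0.49 with its call kept (0.00755), where the offsets shifted all tested genes by a median of −0.092. The calls for the interferon, thymocyte, cell cycle, oxidative phosphorylation and MHC class I lists held without any 1 of the 15 libraries, with the thymocyte median at −0.34 without cDC2 WT 2. The call for maturation ended without cDC1 WT 2 (median 0.41, adjusted p = 0.0689). That for cDC1 markers ended without cDC2 WT 1 (median 0.0068), pDC WT 1 (−0.30) or pDC WT 2 (−0.16), for macrophages without pDC KO 3 or pDC WT 1 (0.0587 and 0.108, medians −0.26 and −0.17), and for cholesterol synthesis without cDC2 WT 1, cDC1 WT 1 or pDC WT 3 (0.0626, 0.104 and 0.0854, medians 0.30, 0.16 and 0.13). Dissociation stress lost its call without 6 of the 15 libraries, with a median of 0.15 without pDC KO 1.

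The other 20 lists did not pass in the average. Median log2 differences were −0.05 for phospholipase C and calcium signalling (mean 0.29, set by Plcb1 and Plcb4), 0.04 for LKB1 complex and AMPK-related kinases, 0.14 for CREB and CRTC targets, and 0.14 for T cell costimulation and Treg-inducing ligands. They were 0.27 for glycolysis and HIF1 targets, 0.03 for fatty acid oxidation, 0.08 for lysosome and autophagy, 0.12 for ATF4 and amino acid response (mean −0.15), −0.01 for p53 targets and 0.21 for NF-kB and inflammatory response. They were −0.10 for cDC2 markers (mean 0.24, raised by Itgam), −0.04 for pDC markers (mean 0.22, raised by Cox6a2), 0.07 for MHC class II presentation and −0.03 for chemokines and chemokine receptors. Among lists of other cells they were 1.88 for NK cells, 0.34 for B cells, 1.05 for monocytes and neutrophils, −0.08 for thymic epithelium and stroma, −1.77 for erythroid cells and −0.14 for sex-linked genes. Camera's adjusted p for these lists ran from 0.0791 (NK cells) to 0.998 (ATF4). Adjusted over their lists alone, Spib (0.78 ± 0.17), Bst2 and Ly6c2 of the pDC markers and Sirpa (0.65 ± 0.17) of the cDC2 markers were higher, and Ccl17 (−2.06 ± 0.45) of the chemokine list was lower. The melanoma list, for the injected tumour, had too few tested genes for a test.

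**Figure D4:**
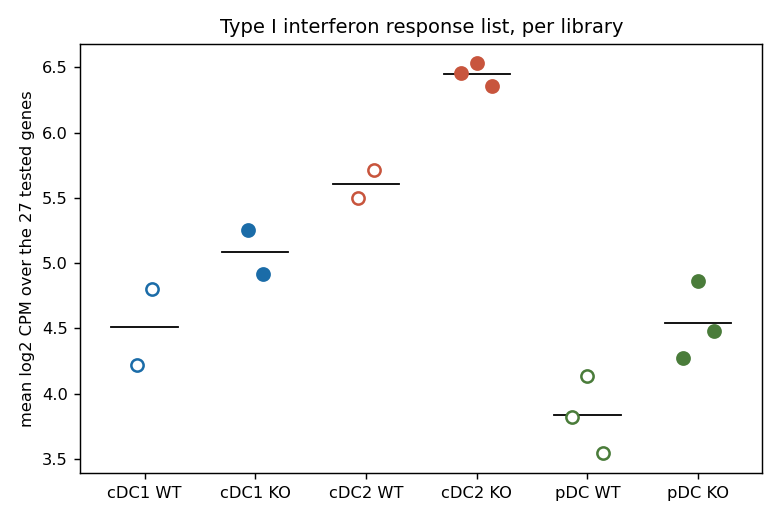
Mean log2 CPM over the 27 tested genes of the type I interferon response list, 1 point per library, with group means as bars. The KO libraries lie above the WT libraries by 0.57 in cDC1, 0.84 in cDC2 and 0.71 in pDC on average, and by 0.71 over the subsets.

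Whether the effect of genotype differed between subsets was tested directly. Mctp2, abundant in pDC at 382 ± 62.1 CPM in KO and 362 ± 88.9 in WT and scarce elsewhere, was the only gene past the threshold, for cDC2 against cDC1 (log2 −5.28 ± 0.81, adjusted p = 0.0472). Its counts were low there: 26 in cDC1 KO against 3 in WT, and 16 in cDC2 KO against 47 in WT. Its call ended without 12 of the 15 libraries, with adjusted p from 0.0638 (without cDC2 WT 2) to 0.344 (without cDC1 WT 2). The comparisons of pDC with cDC1 and of pDC with cDC2 gave 0 genes each in edgeR, with 970 and 988 genes at an unadjusted p under 0.05 (994 for cDC2 against cDC1), and 91 and 33 genes in DESeq2 (42 for cDC2 against cDC1). Cox6a2 differed by −4.51 ± 0.82 between pDC and cDC1 without passing (adjusted p = 0.110). Calls shared between the 3 subsets were few: Plcb1 in all 3, and Itgam in cDC1 and pDC, 2 shared genes where independent lists give 0.00179 (Fisher's exact test, two-sided, p = 9.13e-07, adjusted p = 5.48e-06). For cDC1 with cDC2, and cDC2 with pDC, 1 gene was shared (adjusted p = 0.00766 and 0.0119). Across all tested genes the differences correlated weakly between subsets, with Spearman's rho of −0.0273 for cDC1 with cDC2, −0.0963 for cDC1 with pDC and 0.195 for cDC2 with pDC, over genes that are not independent replicates. Among genes with an unadjusted p under 0.05 in both, the sign was the same in 65 of 83 for cDC1 with cDC2, 29 of 116 for cDC1 with pDC and 179 of 206 for cDC2 with pDC. These comparisons share no libraries, but the labels do not say whether the subsets came from the same mice.

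On simulated counts with the real means and spread, the test recovered 73.1% of 67 genes changed 4-fold in pDC, 79.1% in cDC1 and 82.1% in cDC2, and 7.46%, 5.97% and 7.46% of genes changed 2-fold. The changed genes were drawn only from those above a minimum mean expression in the subset, so recovery among scarcer genes was not measured. Differences of 2-fold in a single gene were therefore mostly below what these groups of 2 and 3 libraries could detect.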

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

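All tests of the explanations weighed here, their rules and the offsets for length and GC content were chosen after the results were seen, and the rules for carried-over cells, for neighbouring genes and for Plcb4 reads were revised once after a first run, while the tests of differences between subsets were planned.

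The genotype effect on Mctp2 differed between cDC2 and cDC1 by −5.28 ± 0.81 on the log2 scale (edgeR, adjusted p = 0.0472), with 16 counts in cDC2 KO against 47 in WT, and 26 in cDC1 KO against 3 in WT. It was the only gene to pass for a difference between subsets, and 12 of the 15 libraries ended the call when left out (adjusted p up to 0.344, without cDC1 WT 2). Mctp2 is abundant in pDC, at 362 ± 88.9 CPM in WT. Siglech, also abundant in pDC, was at 204 CPM in cDC2 WT against 150 in cDC2 KO. In cDC1 it was at 119 CPM in WT against 186 in KO. Ccr9 was lower in KO in both, at 112 against 33.2 CPM in cDC2 and 158 against 137 in cDC1, while Ly6c2 and Atp1b1 were higher in cDC2 KO. A differing share of pDC reads was not tested as a cause of the Mctp2 difference and stays open.

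Gene lists also differed in their genotype effect between subsets by camera, and none of these differences held with an estimated correlation. For cDC2 against cDC1 the median differences were −0.82 for pDC markers (adjusted p = 0.000853, and 0.599 with an estimated correlation), 0.96 for MHC class II presentation (0.000853, and 0.240) and 0.56 for oxidative phosphorylation (0.000853, and 0.987). For pDC against cDC1 they were 0.32 for MHC class II presentation (0.0297, and 0.853), 0.30 for oxidative phosphorylation (0.0147, and 0.894), 0.32 for lysosome and autophagy (0.0297, and 0.853) and 1.02 for chemokines and chemokine receptors (0.0297, and 0.853). For pDC against cDC2 they were 0.33 for cDC1 markers (0.0483, and 0.937) and 0.76 for thymocytes and T cells (0.0360, and 0.937). With the offsets for length and GC content, lists past the threshold numbered 1 for cDC2 against cDC1, 0 for pDC against cDC1 and 2 for pDC against cDC2. Leaving out 1 library at a time gave 2 to 5, 0 to 6 and 0 to 3, with 2 for cDC2 against cDC1 without either cDC2 WT library.

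Itgam and Cox6a2, higher in KO on average by 2.71 and 3.19, flank Itgax, whose promoter drives Cre in these mice. Cells carried over from another sorted subset are argued against as the whole cause in 3 of 4 cases tested. If cDC2 cells gave pDC KO its Itgam (a share of 29.5%), 34 other abundant cDC2 genes would rise with them. Their summed excess was 0.0485 of what that needs (−0.0262 to 0.124 per library, median gene 0.0199). In cDC1 KO, pDC cells at the 3.17% that Cox6a2 needs gave 0.205 for 52 abundant pDC genes (0.131 and 0.278 per library, median gene 0.280), with Siglech at 186 CPM against 752 needed, so a smaller share of pDC stays open. In cDC2 KO, pDC cells at the 1.92% that Cox6a2 needs gave −0.160 for 32 genes (−0.182 to −0.137 per library). Whether cDC2 cells at 4.95% gave cDC1 KO its Itgam stays open, as only 3 abundant cDC2 genes were scarce enough in cDC1, with a summed excess of 0.387 of that needed (0.279 and 0.534 per library). Of these, Cldn12 was at 4.70 CPM against 46.2 needed, Sirpa at 13.8 against 14.8 and the interferon gene Ifit1 at 33.0 against 30.3 (median gene 0.887). A candidate explanation is that the Cre transgene brought extra copies of genes around Itgax: 2 of 5 tested genes within 100 kb of its start were called higher, against 26 of 11741 elsewhere (Fisher's exact test, two-sided, p = 5.46e-05), a count that includes the genes that prompted the test. Itgad, whose span holds Cox6a2 (1.05 ± 0.42, adjusted p = 0.405) was not past the threshold. No library without the transgene lacks LKB1, so loss of LKB1, linked variants and transgene copies stay open and untested against each other. Cells outside the sorted subsets were not tested as a source of Itgam or Cox6a2, and they stay open as well. Itgam encodes CD11b, by which cDC2 were sorted. Cd8a, whose product was used to sort cDC1, was lower in cDC1 KO without passing the threshold over all genes. Whether the gates took the same cells in KO and WT was not tested. Differences within a subset may therefore include a change in which cells were sorted.

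Plcb1 was higher in KO in all 3 subsets, and its neighbour Plcb4 by 1.73 on average. A rise of the whole phospholipase C and calcium list is argued against, since the other 34 members had a median of −0.056 (interquartile range 0.199), and so are Plcb4 reads counted as Plcb1, since even the lowest ratio of Plcb1 to Plcb4 in any KO library (0.0518, in cDC1 KO 1, against 0.188 to 0.680 in pDC KO) would give 37.3 Plcb1 counts in pDC WT where 0 were seen. A local change on chromosome 2 may be a cause, but was not told apart from separate regulation. Plcb1 and Plcb4 were the only neighbouring pair among 36 called genes, against a mean of 0.109 in random lists (permutation p = 0.104, 100000 lists). That permutation counted pairs anywhere in the genome. A single pair therefore could not pass whatever its locus, and the p-value does not decide the question. Tmx4, Mkks and Slx4ip beside them were at −0.11, −0.06 and −0.14. Loss of LKB1, the transgene and variants of the targeted strain at this locus stay open, as the genotype groups carry them together.

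The type I interferon list was higher in KO in every subset, with an average median of 0.77. A trend of counts on transcript length and GC content is argued against as the whole cause, since the median was 0.68 with offsets for both and the list stayed past camera's threshold. Chance differences between libraries are argued against by the mean score per library: genotype permuted within subsets gave an exact p of 0.000833, the smallest that the 1200 assignments can give (adjusted p = 0.0125 over 30 lists), with KO libraries above WT libraries in 3 of 3 subsets. That exact p treats the subsets as separate samples, and the labels do not say whether they share mice. With shared mice fewer assignments would be independent, so the argument against chance holds only for separate mice. The estimated correlation (adjusted p = 0.0540) leaves the list short of a difference from other genes. Reads of other cell types stay open as well and were not tested, though the sort on CD11c with MHC class II, or on Siglec-H for pDC, selects against NK cells and neutrophils: the mean scores of monocytes and neutrophils and of NK cells were 0.55 and 0.84 higher in KO (exact p = 0.0117 and 0.0317, adjusted p = 0.0875 and 0.119), against 0.71 for the interferon list. Loss of LKB1 is consistent with the pattern but untested against the tumour load, the litter or housing of the KO mice, which the labels do not give.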

How the results depend on the processing

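The offsets for length and GC content and the average without the cDC2 libraries were chosen after seeing the data, and the rest were planned. For genes, 4398 of 4912 values over 203 gene comparisons kept their direction and side of the threshold, 412 lost the call, 100 gained one and 2 reversed. Where no construction is named, the cause was not tested.

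DESeq2 called more genes: 14 in cDC1, 222 in cDC2, 137 in pDC, 133 in the average, 42, 91 and 33 for the differences cDC2 minus cDC1, pDC minus cDC1 and pDC minus cDC2, and 1651 for WT cDC2 against cDC1. Its calls held all 3, 14, 8 and 36 edgeR calls of cDC1, cDC2, pDC and the average. Without a filter edgeR called 28, 177, 203 and 166 genes in the same 4, and 38, 118 and 88 for the differences. Voom with sample weights called 10 in cDC1, 0 in cDC2 and 16 for pDC minus cDC1. RLE scaling gave 1 in cDC1 and 5 in cDC2, where it shifted the median of all genes by −0.10. The strict filter gave 1 in cDC1. Without robust spread there were 1 in cDC1, 4 in cDC2 and 0 for cDC2 minus cDC1. With only the groups of the contrast, and so fewer libraries to estimate the spread, there were 2 in cDC2, 2 in pDC, 0 for cDC2 minus cDC1, 102 for WT cDC2 against cDC1 and 1568 for WT pDC against cDC2. A threshold of 0.1 by construction gave 87 in cDC2, 56 in the average and 1741 for WT cDC2 against cDC1. The offsets gave 5 in cDC2 (median shift −0.23), 20 in the average and 682 for WT cDC2 against cDC1. The average without the cDC2 libraries had 3, from fewer samples.

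No pairing of samples by replicate number was seen, but the check cannot exclude it. The 7 pairs of KO and WT with 1 number correlated at −0.150 to 0.0888 after group means were removed. In a group of 2 libraries the deviations from the mean mirror each other. Pairs between such groups therefore repeat the same value and do not count apart. Of 13 pairs of subsets with 1 genotype and number (−0.182 to 0.179), 1 was above 0.1, as were 5 of 13 pairs of 1 number that differ in subset and genotype (−0.149 to 0.142). With the number as a block, 1 gene was called in cDC1, 7 in cDC2 (3 higher and 4 lower), 3 in pDC, 19 in the average and 0 for cDC2 minus cDC1, where a block within genotype also gave 0. The block also ended 4 of 29 list calls by camera in the genotype comparisons. They were cDC2 markers in cDC1 (adjusted p = 0.0539), cDC1 markers in cDC2 (0.0846), and cDC1 markers and dissociation stress in the average (0.0506 each). A sex covariate was not run, since Xist was not among tested genes and all 15 libraries expressed the Y-linked genes. Y-linked reads do not exclude libraries that hold both sexes, so the share of each sex per genotype stays unknown. Ddx3y ranged from 122 to 597 CPM over all libraries.

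Leaving out 1 library at a time, with a lone remaining library assumed to vary like the others, gave 1 to 5 genes in cDC1, 1 to 26 in cDC2, 4 to 22 in pDC, 5 to 50 in the average, 0 to 2, 0 to 2 and 0 to 1 for the differences, and 253 to 1240, 1692 to 3436 and 2105 to 2919 for WT cDC2 against cDC1, pDC against cDC1 and pDC against cDC2. Lists past the threshold numbered 6 to 9 in cDC1, 3 to 8 in cDC2, 2 to 11 in pDC, 7 to 12 in the average and, for WT pDC against cDC1, 8 to 14. Among named genes the sign turned for Ccr7 in cDC1 (−0.13 without cDC1 WT 2, 1.595 without WT 1), Cd8b1 in cDC2 (0.19 without cDC2 WT 2, −1.64 without WT 1). List medians that turned were those of cell cycle in cDC1 (−0.12 without cDC1 WT 2, 0.68 without WT 1), cDC1 markers in cDC2 (0.32 without cDC2 WT 1) and in the average (0.0068 without cDC2 WT 1), thymocytes in cDC2 (0.00058 without cDC2 WT 2) and, with the offsets, MHC class II in cDC2 (−0.09). None was past the threshold once turned.

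With an estimated correlation, 0 lists passed in cDC1, 0 in cDC2, 0 in pDC and 0 in the average, and 3, 4 and 6 in the WT comparisons. Fry called 0, 4, 0 and 3, and 13 and 20 for WT cDC2 against cDC1 and pDC against cDC1. The offsets left 4 lists in cDC2. Genes shared between cDC1 and cDC2 and higher in KO numbered 2 at a threshold of 0.1 and 2 with DESeq2, and cDC2 and pDC shared 9 higher and 3 lower with DESeq2. With groups of this size, a change of 2-fold in 1 gene was mostly not detectable in simulated counts.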

Other observations

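The permutations of list scores were chosen after the results were seen, while the counts over other groupings of the libraries were planned.

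In pDC, the 3 KO against 3 WT libraries gave 8 genes, and the highest of the other 9 splits gave 45. The 10 splits are too few for a share under 0.05, and 2 of them, the real one included, gave at least as many genes. The split with 45 genes set pDC KO 1, KO 2 and WT 3 against KO 3, WT 1 and WT 2, a count several times the real one that points to a structure of these samples beside genotype. The mean scores of dissociation stress also separated that split (8.37, 7.19 and 7.77 against 6.52, 6.61 and 6.95 log2 CPM), as did those of DC maturation (4.77, 4.70 and 4.52 against 3.05, 3.90 and 3.50) and of NF-kB and inflammatory response (6.12, 4.90 and 5.40 against 3.73, 4.49 and 4.16). Of 30 lists 6 did so, where 10% would by chance, and the split was chosen after it was seen.

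For the average, genotype was reassigned within subsets 60 times, the real assignment included. The real one gave 36 genes and the highest other 3, so 1 of 60 gave as many. The 60 were drawn from 1200 possible assignments. Reassigning genotype in each subset apart also treats the subsets as separate mice, which the labels do not say. On that footing chance is unlikely for this count, but it is not excluded.

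Over the 30 lists, 3 had a mean score that differed by genotype with an adjusted p under the threshold (exact permutation within subsets, two-sided). They were interferon response (0.71), MHC class I presentation (0.29, exact p = 0.000833, adjusted p = 0.0125) and phospholipase C and calcium signalling (0.22, exact p = 0.0025, adjusted p = 0.025), which carries Plcb1 and Plcb4. Without those genes, the other 34 members of the calcium list had a median log2 difference of −0.056 in the average. Its score therefore does not show a rise of the whole list. The permutation treats the subsets as separate samples, and the labels do not say whether they share mice. By camera, the average MHC class I list did not pass with an estimated correlation (adjusted p = 0.174) or with the offsets for length and GC content (adjusted p = 0.0547).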
